A study of Mus musculus with 16 samples.

How the data were processed

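RNA was measured in kidney cortex of male mice on a C57Bl/6J background that carried a floxed Degs1 gene. Degs1 encodes dihydroceramide desaturase, the enzyme that turns dihydroceramide into ceramide in the last step of de novo ceramide synthesis. Per the labels, Degs1fl/fl littermates (fl/fl) served as controls for mice with a tamoxifen-inducible global deletion driven by Rosa26-CreERT2 (iGKO). Tamoxifen was given at 3 mg on 5 days at 9 weeks of age and surgery followed at 12 weeks. Surgery was either a sham operation or bilateral ischaemia-reperfusion injury (IRI), in which both renal pedicles were clamped for 28 min and reperfused for 24 h. The 16 samples fell into 4 groups of 4 with 1 batch label. Libraries were stranded and made from total RNA after depletion of ribosomal RNA. In the text a library carries the name of its group and its replicate number, as in iGKO sham 4. The replicates were the separate samples of the labels. The p-values of the gene and list tests rest on the spread between samples within groups, pooled over all 4 groups. This holds also for a comparison of a pair of groups, so libraries outside the pair affect its p-values.

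The deposited values were counts, raw reads per gene as whole numbers, with no normalization, for 56980 Ensembl gene identifiers in 16 libraries. The authors' processing notes name cutadapt 1.16, STAR 2.7.9a, featureCounts 1.6.3, FastQC, Picard, MultiQC and DESeq2 1.36.0 and the genome build GRCm39 (mm39). The role of each tool, the annotation release and the strand setting were not given in the sources used here. Gene symbols, gene types and GC content were taken from a GENCODE annotation of an earlier build, matched by gene identifier, so no coordinates are given. A symbol was found for 52073 identifiers. The 4907 identifiers without a symbol held 0.840% to 1.77% of the counts of a library and stayed in the tests but were not named.

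Total counts ranged from 12704273 to 18816343 per library. The floor for a gene with no reads in a group was set at 3 counts over the group. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Expression levels are counts-per-million values with TMM scaling (CPM), given as the mean ± SD over the 4 libraries of a group.

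Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as its argument, which left 17972 genes. Libraries were scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 16 libraries. There were 5 contrasts: IRI against sham in fl/fl, IRI against sham in iGKO, iGKO against fl/fl after sham, iGKO against fl/fl after IRI, and the genotype by operation interaction, which is the response in iGKO minus the response in fl/fl. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the root of the quasi-likelihood F value. Adjusted p-values of single genes come from this edgeR model unless another tool is named. A gene is called when it passes the threshold.

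The design, the 37 gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. The named genes were Degs1 and, in each comparison of a pair of groups, the 10 genes with the largest rise and the 10 with the largest fall among the called genes. These had to reach a mean of 1 CPM over all libraries, show no overlap between the groups and have an established symbol. For the interaction the rule took the 10 genes of each sign with the smallest p among the called genes. Where fewer than 5 genes passed, genes were named from the 5 with the smallest p and said not to pass. Up to 4 members of each described list, those with the smallest p, were added. The anchor genes Havcr1, Lcn2, Slc34a1, Umod, Ppargc1a, Degs2, Sptlc2, Cers6, Immt, Chchd3, Il6, Ccl2 and Cdkn1a were added whatever their result. Il6 did not pass the filter on low counts and was not tested.

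The lists held 698 genes, of which 664 were tested. They covered tubular injury markers, ceramide de novo synthesis, ceramide use and breakdown, complex I subunits, complex II, III and IV subunits, ATP synthase subunits, mitochondrially encoded mRNAs, and the cristae and MICOS complex. Further lists held mitochondrial fusion, fission and mitophagy, mitochondrial biogenesis regulators, fatty acid oxidation, the tricarboxylic acid cycle, glycolysis and hypoxia response, and cholesterol synthesis. Others held immediate early genes, the integrated stress and unfolded protein response, the heat shock response, the NRF2 and antioxidant response, the p53 response, regulated cell death, the cell cycle, cytokines and chemokines, interferon-stimulated genes, lysosome and autophagy, and extracellular matrix and fibrosis. The 12 cell type lists marked the proximal tubule, thick ascending limb, distal convoluted and connecting tubule, collecting duct, podocyte, endothelium, fibroblast and mural cell, neutrophil, monocyte and macrophage, lymphocyte, and erythrocyte, with a last list for adrenal, fat, muscle and urothelium as possible neighbours of the tissue piece. Each list was tested against the other genes with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the 37 lists of a comparison. Beside each called list stands the adjusted p with an estimated correlation, and no list in any of the 5 comparisons passed with it. The rotation test fry, which asks whether the genes of a list move 1 way on balance, was run as another alternative. A list score is the mean of log2(CPM + 1) over the measured members in a library, with a pseudocount of 1, compared by exact two-sided permutation tests. With 4 libraries against 4, the smallest p of such a test is 0.0286.

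The alternatives were DESeq2 size factors in place of TMM, no filter, a stricter filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, removal of the mitochondrially encoded genes, a fit to the compared groups alone, other pseudocounts, and leaving out each library in turn. Offsets corrected for GC content and a fit without iGKO sham 4 and iGKO IRI 4, the libraries of lowest mitochondrially encoded share, were chosen after seeing the data, as was leaving out libraries outside the compared groups. List scores and library measures with a library left out were not planned. Nor were other list score settings for IRI against sham and for the interaction. No sample was left out of the analysis reported here. The procedure was tested on simulated data drawn from the means, dispersions and depths of these libraries. Each simulated gene had the same dispersion in all libraries, so the unequal spread of the real libraries was not reproduced. The changed genes were drawn from genes with a mean of at least 1 CPM, so recovery at lower levels was not tested. Recovery in the real data may differ. With 100 genes changed by 4-fold, edgeR recovered 84 in fl/fl, 93 in iGKO, 89 after sham, 91 after IRI and 71 in the interaction. For 2-fold changes it recovered 38, 36, 53, 46 and 8 of 100 in the same order. False calls made up 3.66% to 7.79% of its calls. On simulated IRI against sham in fl/fl, 18.0% of the calls of DESeq2 and 4.10% of those of limma voom were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.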

Results

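RNA was sequenced from kidney cortex of male mice in 16 samples, 4 in each of 4 groups: fl/fl sham, iGKO sham, fl/fl IRI and iGKO IRI. Total counts were 13281659, 16263764, 14336404 and 14573599 in fl/fl sham 1 to 4, and 13627274, 16735829, 18816343 and 15210971 in iGKO sham 1 to 4. They were 14442184, 14528975, 13613209 and 16953513 in fl/fl IRI 1 to 4, and 12704273, 14902635, 15077208 and 14805417 in iGKO IRI 1 to 4. Between 24328 and 25818 genes had at least 1 read in a library. Mitochondrially encoded genes took 4.43% to 6.48% of counts in fl/fl sham, 2.99% to 5.37% in fl/fl IRI and 2.05% to 4.51% in iGKO IRI. In iGKO sham they took 6.07%, 6.30% and 6.45% in 3 libraries and 0.443% in iGKO sham 4. In 16 exact two-sided permutation tests of total counts, mitochondrial shares and the share of the 10 most abundant genes, the smallest p was 0.0571 and all adjusted values were at least 0.522. The first principal component held 32.9% of the variance and placed fl/fl IRI 2, 3 and 4 apart from all other libraries. The second held 15.8%, with iGKO sham 4 at the lowest value, -82.6, followed by iGKO IRI 4 at -44.0. In the injury marker genes Havcr1 and Krt20, fl/fl IRI 1 stood at 101 and 10.3 CPM, against 710 to 1666 and 115 to 894 CPM in the other fl/fl IRI libraries.

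Degs1 (ENSMUSG00000038633) was the gene targeted in iGKO mice, and its RNA served as a check of the labels. After sham its level was 100.3 ± 12.3 CPM in fl/fl and 57.0 ± 14.3 CPM in iGKO (SD, n = 4 each), 56.8% of the control level. After IRI it was 113 ± 18.2 CPM in fl/fl and 54.5 ± 6.81 CPM in iGKO, 48.4% of the control level. No iGKO library reached any fl/fl library: the ranges were 40.2 to 71.7 against 84.0 to 113 CPM after sham, and 44.7 to 59.8 against 88.8 to 133 CPM after IRI. The exact two-sided permutation test of 4 libraries against 4 gave p = 0.0286 after each operation, the smallest that it can give. Over all genes, Degs1 fell by 1.05 ± 0.18 (SE) on the log2 scale after IRI with an adjusted p of 0.0325, and the value of -0.82 ± 0.18 after sham had an adjusted p of 0.9999. Its call after IRI was lost without fl/fl sham 4 (adjusted p = 0.0508), fl/fl IRI 3 (0.0865), fl/fl IRI 4 (0.0994), iGKO IRI 1 (0.0734), iGKO IRI 2 (0.0943) or iGKO IRI 3 (0.133), with log2 values between -1.15 and -0.96 over all 16 left-out libraries. Reads outside the deleted part of the gene still count towards Degs1, so the remaining level is not a measure of recombination.

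**Figure D1:**
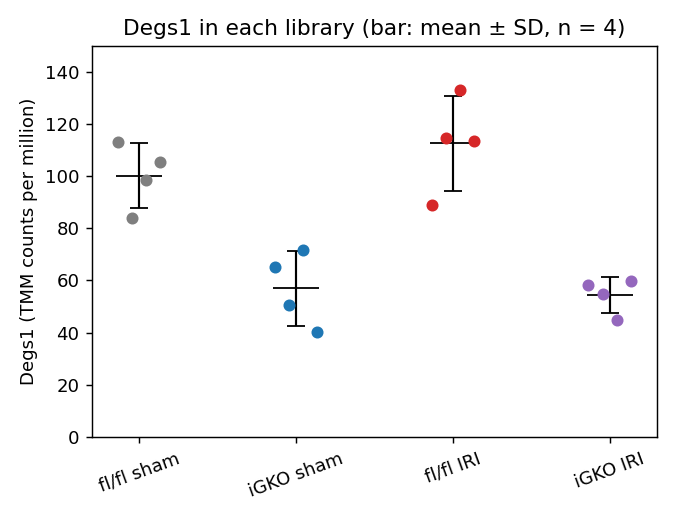
Degs1 in TMM-scaled CPM in each of the 16 libraries, with points for libraries and black bars for the mean ± SD of each group of 4. The iGKO libraries lie between 40.2 and 71.7, below the fl/fl libraries, which lie between 84.0 and 133.

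The comparison of IRI with sham in fl/fl gave the response of control kidneys to ischaemia at 24 h. Havcr1 (ENSMUSG00000040405), the injury marker KIM-1 of proximal tubule, rose from 11.9 ± 8.90 to 950 ± 691 CPM (n = 4 each), a log2 fold change of 6.32 ± 0.97 (SE) with an adjusted p of 0.00117. Krt20, a keratin, rose from 1.95 ± 2.02 to 373 ± 400 CPM. Lcn2, the iron-siderophore binding protein NGAL, rose from 10.3 ± 6.79 to 249 ± 157 CPM, and Sox9, a transcription factor of repairing tubule cells, from 2.42 ± 0.577 to 85.2 ± 95.5 CPM. Slc34a1, the sodium-phosphate cotransporter of the proximal tubule, fell from 5087 ± 338 to 1995 ± 1293 CPM, and Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, from 573 ± 133 to 126 ± 79.1 CPM.

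Of 28 measured tubular injury markers, 23 rose and none fell (25 adjusted over the list alone), with a median log2 fold change of 2.79 (adjusted p = 2.73e-27, adjusted p = 0.0611 with an estimated correlation). Among them, Spp1, which encodes osteopontin, rose from 677 ± 300 to 6599 ± 3037 CPM, and Clu, which encodes the extracellular chaperone clusterin, from 217 ± 39.6 to 1349 ± 719 CPM. Plaur, the urokinase receptor, rose by 4.23 on the log2 scale and Tnfrsf12a, the receptor of TWEAK, by 3.51. Immediate early genes, which are rapidly induced and many of which encode transcription factors, rose in 17 of 20 (20 adjusted over the list alone, median 2.26, adjusted p = 1.28e-21, adjusted p = 0.0683 with an estimated correlation). Examples were Jun, from 39.1 ± 4.98 to 158 ± 62.0 CPM, Myc, from 7.69 ± 1.25 to 62.4 ± 38.8 CPM, Atf3 at a log2 value of 3.29 and Junb at 2.29. Of 18 cytokines and chemokines, 9 rose (12 adjusted over the list alone, median 2.36, adjusted p = 4.77e-08, adjusted p = 0.095 with an estimated correlation). Among them were the neutrophil attractants Cxcl1, from 1.72 ± 0.774 to 32.8 ± 23.5 CPM, and Cxcl2, from 0.513 ± 0.660 to 15.9 ± 7.04 CPM. Lif and Cxcl10 rose by 3.97 and 2.23 on the log2 scale. Neutrophil markers rose in 9 of 10 (10 adjusted over the list alone, median 3.70, adjusted p = 4.87e-07, adjusted p = 0.213 with an estimated correlation). S100a9, a calcium-binding protein of granulocytes, rose from 1.39 ± 0.558 to 25.2 ± 25.2 CPM. Il1r2, Mmp8 and S100a8 were the others of smallest p, at log2 values of 4.18, 4.26 and 3.97. Of 16 monocyte and macrophage markers, Cd14, a receptor for bacterial lipopolysaccharide, and Chil3 rose (2 adjusted over the list alone), and the list had an adjusted p of 0.0833. With a single library left out this adjusted p ran from 0.000525 to 0.806, the latter without fl/fl IRI 1.

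The p53 response list had 9 of 17 genes higher (12 adjusted over the list alone, median 0.92, adjusted p = 3.17e-06, adjusted p = 0.0683 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 10.7 ± 2.22 to 123 ± 127 CPM. Plk3, Tnfrsf10b and Aen rose by 1.65, 1.59 and 0.99 on the log2 scale. Regulated cell death genes rose in 8 of 18 (8 adjusted over the list alone, median 0.47, adjusted p = 0.000138, adjusted p = 0.0683 with an estimated correlation). Mlkl, the effector of necroptosis, rose from 2.81 ± 0.114 to 8.76 ± 3.67 CPM, and Casp8, Tnfrsf1a and Bak1 rose at log2 values of 0.95, 1.28 and 0.78. The integrated stress and unfolded protein response list had 8 genes higher and 1 lower of 21 (9 and 2 adjusted over the list alone, median 0.53, adjusted p = 0.00153, adjusted p = 0.0968 with an estimated correlation). Its genes of smallest p were Asns, an asparagine synthetase, Chac1, a glutathione-degrading enzyme, and the transcription factors Xbp1 and Atf5, at log2 values of 2.49, 4.00, 1.46 and 1.08. The heat shock response list had 6 of 15 higher (8 higher and 1 lower adjusted over the list alone, median 0.44, adjusted p = 0.00106, adjusted p = 0.257 with an estimated correlation). Hspb1, a small heat shock protein, rose from 8.41 ± 0.498 to 76.5 ± 43.4 CPM. Of 19 NRF2 and antioxidant genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.0419, adjusted p = 0.467 with an estimated correlation). Hmox1, the haem-degrading oxygenase, rose from 32.9 ± 7.83 to 276 ± 183 CPM, Slc7a11 and Srxn1 rose by 4.42 and 2.25 on the log2 scale, and Sod2, the mitochondrial superoxide dismutase, fell by 0.86. The NRF2 list was no longer called without fl/fl sham 3 (adjusted p = 0.108), fl/fl sham 4 (0.0620), iGKO sham 4 (0.0503), fl/fl IRI 2 (0.0980) or fl/fl IRI 4 (0.0748). Of 20 extracellular matrix genes 5 rose (5 adjusted over the list alone, median 0.53, adjusted p = 0.00608, adjusted p = 0.337 with an estimated correlation). Tnc, which encodes tenascin C, rose from 11.2 ± 2.66 to 75.9 ± 55.6 CPM, and Ccn1 and Tgfb1 rose at log2 values of 2.11 and 1.00.

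Of 28 proximal tubule markers 16 fell (26 adjusted over the list alone, median -1.19, adjusted p = 8.04e-16, adjusted p = 0.0968 with an estimated correlation). Cubn, an endocytic receptor, fell from 1420 ± 124 to 543 ± 199 CPM, and Slc22a8, Slc3a1 and Fbp1 fell by 1.26, 0.98 and 1.59 on the log2 scale. Of 10 thick ascending limb markers 6 fell (8 adjusted over the list alone, median -1.31, adjusted p = 2.05e-07, adjusted p = 0.095 with an estimated correlation), including the potassium channel gene Kcnj1, from 168 ± 8.36 to 70.3 ± 35.5 CPM. Umod, the uromodulin gene of the same list, stood at 1779 ± 128 CPM after sham and 1371 ± 472 CPM after IRI with an adjusted p of 0.395. Of 10 distal convoluted and connecting tubule markers 5 fell (8 lower and 1 higher adjusted over the list alone, median -0.995, adjusted p = 3.59e-05, adjusted p = 0.0968 with an estimated correlation). Kl, which encodes klotho, fell from 922 ± 83.9 to 320 ± 227 CPM, and Calb1, Klhl3 and Slc8a1 fell by 1.49, 1.65 and 1.12 on the log2 scale. Collecting duct markers fell in 2 of 15 (2 adjusted over the list alone, median -0.49, adjusted p = 0.00972, adjusted p = 0.19 with an estimated correlation). Both, Slc4a1 and Scnn1a, lost their call without fl/fl sham 1 (0.0531 and 0.0677), 2 (0.0536 and 0.0580) or 4 (0.0582 and 0.103), without fl/fl IRI 2 (0.0671 and 0.0907) or 3 (0.0740 and 0.0914), and when the compared groups were fitted alone (0.0774 and 0.107).

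In complex I, 14 of 37 nuclear-encoded subunits fell (19 adjusted over the list alone, median -0.48, adjusted p = 4.57e-09, adjusted p = 0.257 with an estimated correlation). Ndufv3 fell from 90.5 ± 2.17 to 50.5 ± 11.0 CPM and Ndufa6 from 92.1 ± 6.66 to 50.5 ± 6.33 CPM. In complexes II, III and IV, 8 of 23 fell (10 adjusted over the list alone, median -0.49, adjusted p = 2.43e-06, adjusted p = 0.257 with an estimated correlation). Cox5b fell from 128 ± 9.22 to 76.1 ± 6.76 CPM. ATP synthase subunits fell in 4 of 16 (6 adjusted over the list alone, median -0.40, adjusted p = 0.000138, adjusted p = 0.278 with an estimated correlation). Of these, Atp5o, Atp5k and Atp5c1 lost their call without fl/fl sham 1 (0.0581, 0.0845 and 0.0882), fl/fl IRI 3 (0.0687, 0.0945 and 0.101) or fl/fl IRI 4 (0.0531, 0.0797 and 0.0635). Genes of the tricarboxylic acid cycle fell in 6 of 17 (11 adjusted over the list alone, median -0.48, adjusted p = 2.86e-06, adjusted p = 0.257 with an estimated correlation). Ogdh, a subunit of the oxoglutarate dehydrogenase complex, fell by 0.84 on the log2 scale. The calls of Dlst and Sucla2 in this list were lost without fl/fl sham 1 (0.0648 and 0.0806), 3 (0.0558 and 0.0950) or 4 (0.0580 and 0.0697) or fl/fl IRI 3 (0.0751 and 0.0964). Of 13 cristae and MICOS genes 4 fell (4 adjusted over the list alone, median -0.22, adjusted p = 0.018, adjusted p = 0.337 with an estimated correlation). All 4, Chchd3, Opa1, 2410015M20Rik and Apoo, lost their call without fl/fl sham 1 (0.107, 0.0735, 0.0832 and 0.103), 3 (0.0552, 0.0641, 0.0780 and 0.115) or 4 (0.0989, 0.0807, 0.0742 and 0.103), or without fl/fl IRI 3 (0.0938, 0.0945, 0.103 and 0.121) or 4 (0.0894, 0.0799, 0.0718 and 0.109). Immt, the core MICOS subunit mitofilin, stood at 291 ± 11.6 CPM after sham and 242 ± 16.1 CPM after IRI with an adjusted p of 0.228. Chchd3, another MICOS subunit, fell from 95.6 ± 9.75 to 68.2 ± 15.7 CPM (adjusted p = 0.0388), a call also lost without fl/fl sham 2 (0.0574), iGKO sham 1 (0.0514) or 2 (0.0511), fl/fl IRI 2 (0.0611) or iGKO IRI 3 (0.0511). It was also lost with the replicate number as a block (0.0544), with no filter (0.0866) and when the compared groups were fitted alone (0.110). Ppargc1a, the master regulator of mitochondrial biogenesis, fell from 126 ± 13.4 to 58.4 ± 16.7 CPM (log2 -1.10 ± 0.21, adjusted p = 0.00343). In its list 4 of 17 genes fell and Pprc1 rose (5 and 1 adjusted over the list alone, median -0.19, adjusted p = 0.0399, adjusted p = 0.322 with an estimated correlation), and the list was no longer called without fl/fl sham 2 (adjusted p = 0.0641) or fl/fl IRI 3 (0.113). Of 31 fatty acid oxidation genes 3 fell and 1 rose (3 and 1 adjusted over the list alone, median -0.15, adjusted p = 0.0451, adjusted p = 0.646 with an estimated correlation), a call lost without fl/fl sham 2 (adjusted p = 0.223) or fl/fl IRI 3 (0.880). The 13 mitochondrially encoded mRNAs had a median of -0.48 and none was called (none adjusted over the list alone, list adjusted p = 0.159). The list was called as lower without iGKO sham 4 (adjusted p = 0.0168), a library outside this comparison. Cholesterol synthesis genes fell in 6 of 20 (10 adjusted over the list alone, median -0.57, adjusted p = 4.8e-05, adjusted p = 0.322 with an estimated correlation). Hmgcs1, the synthase before the rate-limiting step, fell from 677 ± 83.5 to 250 ± 155 CPM, and Idi1 fell by 1.67 on the log2 scale.

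In ceramide de novo synthesis, 1 of 15 genes was called (1 adjusted over the list alone, list adjusted p = 0.305). This was Sptlc2, a subunit of serine palmitoyltransferase at the entry of the pathway, which rose from 109 ± 9.03 to 280 ± 128 CPM (adjusted p = 0.00214). The ceramide synthase gene Cers6 had a log2 value of -0.19 (adjusted p = 0.541), the paralog Degs2 -0.22 (0.708) and Degs1 0.17 (0.565). Of 27 genes of ceramide use and breakdown 4 rose and 2 fell (6 and 2 adjusted over the list alone, list adjusted p = 0.887): Sphk1, a sphingosine kinase, rose from 4.32 ± 1.02 to 53.7 ± 62.1 CPM, and Sgpp1, a sphingosine 1-phosphate phosphatase, and Asah2, a neutral ceramidase, fell by 1.18 and 0.69 on the log2 scale.

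The other lists were smaller or were not called. Lysosome and autophagy genes rose in 8 and fell in 2 of 24 (8 and 3 adjusted over the list alone), with Ctsd and Ctsb, which encode cathepsins, rising by 0.89 and 0.75 on the log2 scale, and the list had an adjusted p of 0.131. Lymphocyte markers fell in 1 of 8 (1 adjusted over the list alone, median -0.88, adjusted p = 0.0199, adjusted p = 0.337 with an estimated correlation), a list call lost without fl/fl IRI 2 (adjusted p = 0.0710). The adjusted p of the list was 0.0965 for mitochondrial fusion, fission and mitophagy, 0.585 for glycolysis and hypoxia response, 0.371 for the cell cycle, 0.274 for interferon-stimulated genes and 0.302 for the podocyte. It was 0.134 for endothelium, 0.111 for fibroblast and mural cell, 0.91 for the erythrocyte and 0.196 for adrenal, fat, muscle and urothelium. With a single library left out, some of these lists were called. The ranges were 0.0347 to 0.318 for lysosome and autophagy and 0.0445 to 0.206 for mitochondrial fusion, fission and mitophagy. They were 0.0284 to 0.328 for fibroblast and mural cell and 0.0212 to 0.348 for adrenal, fat, muscle and urothelium. Adjusted over the list alone, 2 genes were lower in mitochondrial fusion, fission and mitophagy, 2 were higher in glycolysis and hypoxia response, 1 was lower in each of podocyte and fibroblast and mural cell, and 4 were lower and 1 higher in endothelium. Over all genes the counts were the same except that no endothelial gene was higher, and the other 4 lists had none by either count. The called genes of these lists included Slc2a1, the glucose transporter GLUT1, which rose by 1.46 on the log2 scale, and the endothelial genes Ehd3 and Ptprb, which fell by 0.80 and 0.62. Ccl2, a monocyte attractant, had a log2 value of 1.59 with an adjusted p of 0.108.

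The remaining genes named by the size of their change were as follows. Vgf, a neuropeptide precursor, had no reads in fl/fl sham and was at least 107-fold higher after IRI, against a floor of 3 counts over the group. Mmp7, Fosl1, Sprr2g, Fgb and Fcrlb rose by 6.36, 6.20, 6.06, 6.02 and 5.16 on the log2 scale. Slc6a19os, annotated antisense to a transporter gene, had a value of 5.62, which is uncertain because the strand setting was not given in the sources used here. The falls were Kcng1, Frmpd3, Clec3b, A4gnt, Rnf212b, Col6a6, Kcnt1 and Slco4c1 at log2 values of -5.18, -4.42, -3.62, -3.40, -3.38, -3.26, -3.01 and -2.98. Vmn1r19 and Vmn1r20, at -3.27 and -3.23, belong to a multigene family whose reads can be shared. The call was lost for Kcng1 without fl/fl sham 3 (adjusted p = 0.0511), for A4gnt without fl/fl IRI 3 (0.0573) and for Col6a6 without fl/fl IRI 3 (0.0589). For Clec3b it was lost without fl/fl sham 1 (0.0700), 3 (0.152) or 4 (0.0746), iGKO sham 1 (0.0585), fl/fl IRI 1 (0.0665), 2 (0.0741), 3 (0.0987) or 4 (0.120), or iGKO IRI 3 (0.0559), and for Kcnt1 without fl/fl sham 2 (0.0589) or 3 (0.127) or fl/fl IRI 1 (0.0560), 2 (0.0815) or 3 (0.101). With limma voom the call was lost for Clec3b (0.212), Kcnt1 (0.144) and Slco4c1 (0.0613), and with the compared groups fitted alone for A4gnt (0.0662).

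In all, edgeR called 2779 of 17972 genes, 1520 higher and 1259 lower after IRI, of which 1493 changed at least 2-fold. Of the called genes, 2197 had no overlap between the groups. Over all tested genes the share without overlap was 19.5%, where chance gives 2.86%. The count was 1691 without fl/fl sham 1, 1452 without fl/fl sham 3, 1597 without fl/fl sham 4, 1459 without fl/fl IRI 3, 1850 without fl/fl IRI 4 and 4335 without fl/fl IRI 1. It was 4593 with limma voom and 1526 when the compared groups were fitted alone, a fit in which Slc34a1 had an adjusted p of 0.0665 and Klhl3 of 0.0547.

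**Figure D2:**
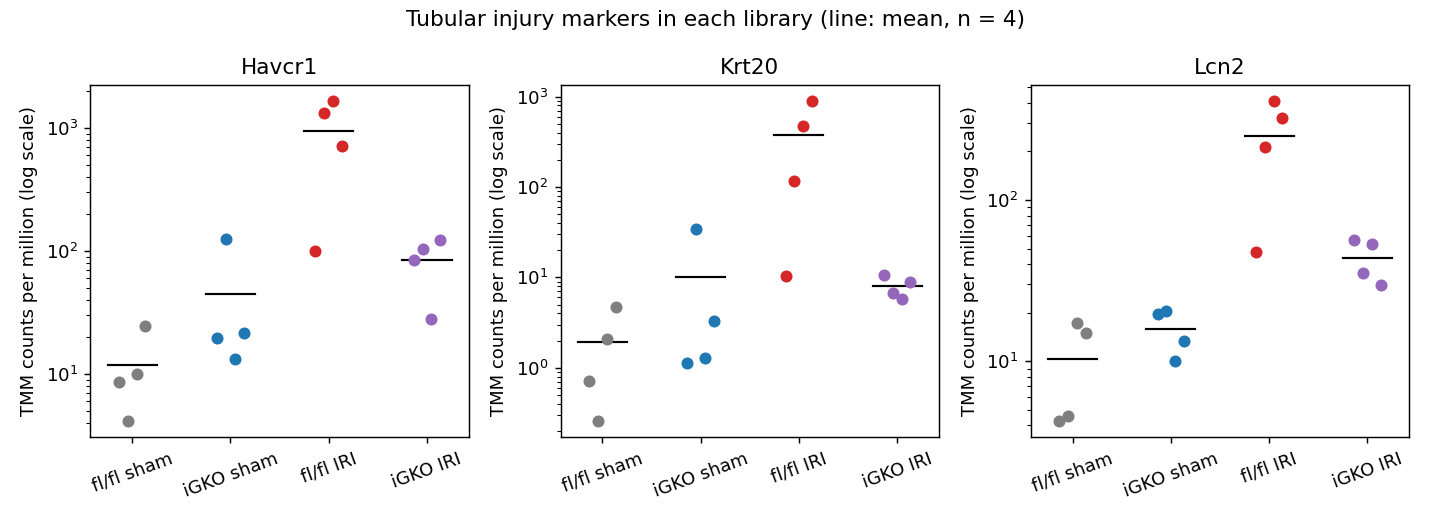
Havcr1, Krt20 and Lcn2 in TMM-scaled CPM on log axes, with points for libraries and lines for the mean of each group of 4. In Havcr1, fl/fl IRI 1 lies at 101 and the other fl/fl IRI libraries at 710 to 1666, while the iGKO IRI libraries lie between 28.0 and 122.

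The comparison of IRI with sham in iGKO gave the response of knockout kidneys. No gene passed the test. The 5 genes of smallest p, none of which passed, were the efflux transporter gene Abcc3, at 5.98 ± 0.731 CPM after sham and 17.5 ± 5.98 CPM after IRI (n = 4 each), the actin-capping gene Capg, at 16.8 ± 2.43 and 40.5 ± 11.4 CPM, Igdcc4, Cd300lf, and the macrophage scavenger receptor gene Stab1, at 69.5 ± 12.4 and 148 ± 44.8 CPM. Havcr1 stood at 45.0 ± 53.8 CPM after sham and 84.6 ± 40.8 CPM after IRI (log2 0.91 ± 0.78, adjusted p = 0.973), and Lcn2 at 15.9 ± 4.99 and 43.7 ± 13.2 CPM (adjusted p = 0.657). Slc34a1 stood at 4554 ± 653 and 3319 ± 455 CPM (adjusted p = 0.945) and Cdkn1a at 12.5 ± 3.24 and 27.9 ± 6.06 CPM (adjusted p = 0.751).

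As groups, several lists moved against the other genes. Of 28 tubular injury markers 26 had a positive fold (median 0.83, adjusted p = 1.05e-12, adjusted p = 0.11 with an estimated correlation), and none was called, also when adjusted over the list alone. All 16 monocyte and macrophage markers were positive (median 1.02, adjusted p = 5.17e-13, adjusted p = 0.11 with an estimated correlation). All 18 cytokines and chemokines were positive (median 1.00, adjusted p = 3.7e-10, adjusted p = 0.108 with an estimated correlation), as were all 10 neutrophil markers (median 1.51, adjusted p = 1.82e-07, adjusted p = 0.205 with an estimated correlation), with none called and none adjusted over the list alone. Extracellular matrix genes were positive in 19 of 20, with none called over all genes and 10 higher adjusted over the list alone (median 1.15, adjusted p = 3.54e-12, adjusted p = 0.108 with an estimated correlation). Tnc in this list stood at 17.2 ± 6.46 and 73.2 ± 30.4 CPM (adjusted p = 0.217). The collagen gene Col1a1 reached 3598 CPM in iGKO IRI 2, against 364 to 900 CPM in the other iGKO IRI libraries, and without iGKO IRI 2 the matrix list had an adjusted p of 5.64e-06. Immediate early genes were positive in 19 of 20, with none called and 4 higher adjusted over the list alone (median 0.62, adjusted p = 5.41e-10, adjusted p = 0.189 with an estimated correlation), among them Fos at 1.71 ± 0.472 and 7.53 ± 3.69 CPM. Proximal tubule markers were negative in 27 of 28 (median -0.45, adjusted p = 2.3e-08, adjusted p = 0.356 with an estimated correlation) and distal convoluted and connecting tubule markers in 10 of 10 (median -0.36, adjusted p = 0.00229, adjusted p = 0.282 with an estimated correlation), with none called and none adjusted over the list alone.

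Smaller shifts were called for complex I (median -0.14, adjusted p = 3.02e-05, adjusted p = 0.439 with an estimated correlation), for complexes II, III and IV (median -0.18, adjusted p = 6.93e-05, adjusted p = 0.439 with an estimated correlation). They were also called for the p53 response (median 0.22, adjusted p = 0.00157, adjusted p = 0.189 with an estimated correlation) and the integrated stress response (median 0.23, adjusted p = 0.00609, adjusted p = 0.189 with an estimated correlation). The last 7 called lists each lost their call without 1 library. For ATP synthase (median -0.17, adjusted p = 0.00282, adjusted p = 0.439 with an estimated correlation) these were iGKO IRI 1 (0.105) and iGKO IRI 2 (0.0884), and for the tricarboxylic acid cycle (median -0.23, adjusted p = 0.000622, adjusted p = 0.439 with an estimated correlation) iGKO IRI 2 (0.0526). For regulated cell death (median 0.22, adjusted p = 0.00229, adjusted p = 0.11 with an estimated correlation) the library was iGKO sham 4 (0.0558). For interferon-stimulated genes (median 0.22, adjusted p = 0.00816, adjusted p = 0.439 with an estimated correlation) they were iGKO sham 2 (0.160), iGKO IRI 1 (0.0618) and iGKO IRI 3 (0.0899). For fatty acid oxidation (median -0.15, adjusted p = 0.0322, adjusted p = 0.676 with an estimated correlation) they were iGKO sham 1 (0.0501), 3 (0.148) and 4 (0.0529) and iGKO IRI 2 (0.582). For the cell cycle (median 0.22, adjusted p = 0.0253, adjusted p = 0.664 with an estimated correlation) they were iGKO sham 1 (0.0548), 3 (0.469) and 4 (0.0970) and iGKO IRI 2 (0.559) and 4 (0.0677). For adrenal, fat, muscle and urothelium (median 1.93, adjusted p = 0.0222, adjusted p = 0.512 with an estimated correlation) they were iGKO sham 2 (0.106) and 4 (0.267) and iGKO IRI 2 (0.0919) and 3 (0.626), where the fat genes Adipoq and Cfd reached 38.0 and 555 CPM in iGKO IRI 3. The other 18 lists were not called. Among them, mitochondrially encoded mRNAs had an adjusted p of 0.125, which was 1.62e-16 (lower) without iGKO sham 4 and 0.921 (higher) without iGKO sham 3. Further uncalled lists also crossed the threshold with 1 library left out. The ranges were 7.80e-05 to 0.989 for fibroblast and mural cell and 0.0167 to 0.379 for mitochondrial biogenesis regulators. They were 0.0201 to 0.505 for cristae and MICOS and 0.0475 to 0.726 for NRF2.

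The count of 0 came from edgeR, with 1145 genes at an unadjusted p under 0.05 and 899 such genes by chance. Leaving out a library of this comparison moved the number from 1145 to between 826 (without iGKO sham 3) and 2200 (without iGKO sham 4). Without iGKO sham 4 still no gene was called, and the smallest adjusted p was 0.124. DESeq2 called 43 genes and limma voom 550. Without iGKO IRI 4 edgeR called 1 gene, Abcc3 (adjusted p = 0.0453). Of the 1520 genes that rose in fl/fl, 1308 had the same sign in iGKO, with medians of 1.00 in fl/fl and 0.22 in iGKO, and 246 of them had an unadjusted p under 0.05 in iGKO. Of the 1259 that fell, 1133 had the same sign, with medians of -1.12 and -0.31. These genes were selected on their fold in fl/fl, so smaller values in iGKO are partly expected from the selection. Across all genes, which are not independent replicates, the folds in the genotypes had a Pearson r of 0.355 and a Spearman rho of 0.430.

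**Figure D3:**
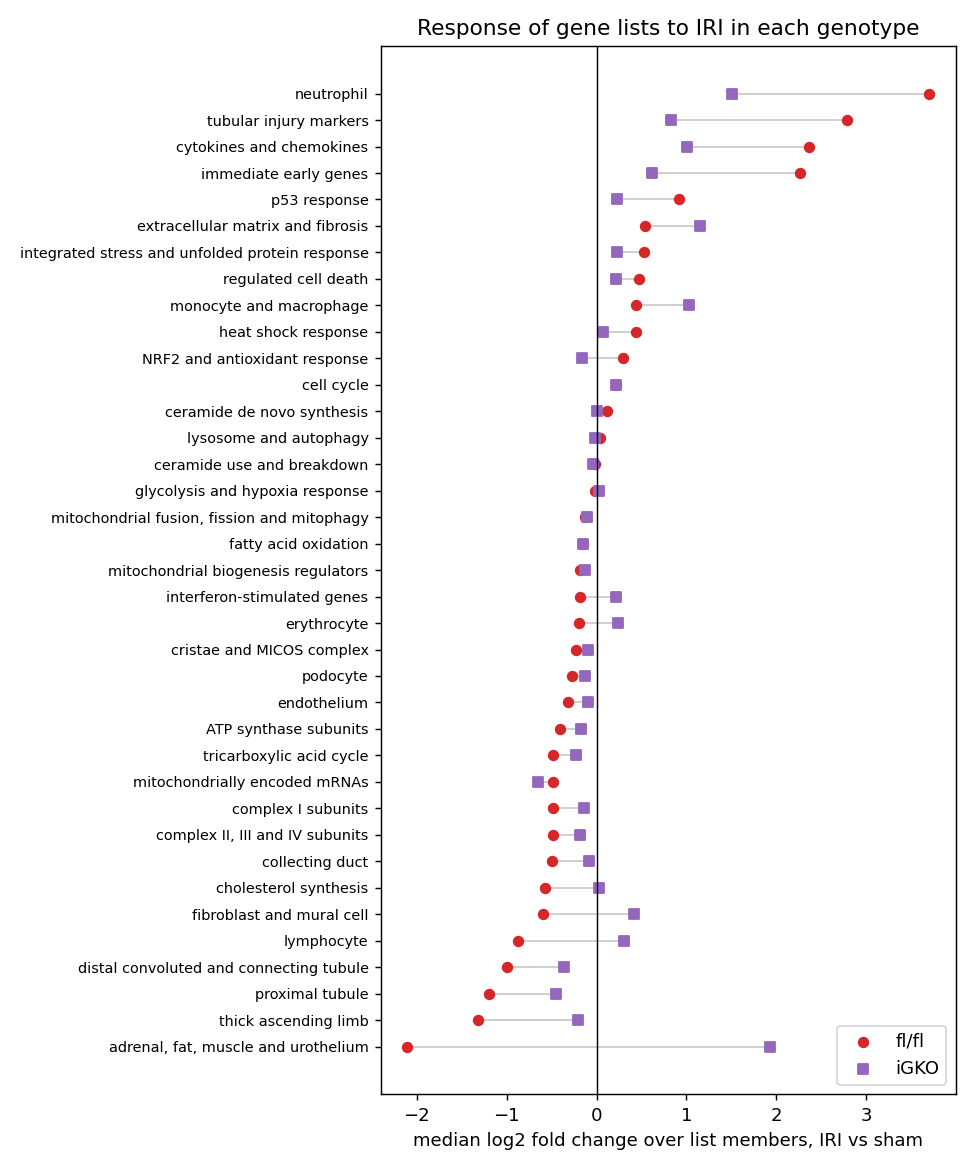
Median log2 fold change of IRI against sham over the measured members of each of the 37 gene lists, with circles for fl/fl and squares for iGKO. Tubular injury markers lie at 2.79 in fl/fl and 0.83 in iGKO, and proximal tubule markers at -1.19 and -0.45.

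The comparison of iGKO with fl/fl after sham gave the effect of the knockout without ischaemia. No gene passed the test. Degs1, at -0.82 on the log2 scale, had the second smallest p. The other genes of smallest p, none of which passed, were Apoh, a plasma lipid-binding glycoprotein, at 8.81 ± 1.71 CPM in fl/fl and 21.5 ± 4.95 CPM in iGKO (n = 4 each), Ces1g, a carboxylesterase, at 11.0 ± 14.3 and 2.13 ± 0.793 CPM, Fbl, which encodes fibrillarin, at 26.1 ± 1.32 and 37.0 ± 4.90 CPM, and Spns2, a sphingosine 1-phosphate exporter, at 71.4 ± 8.70 and 123 ± 14.7 CPM. Their adjusted p was 0.9999. Havcr1 stood at 11.9 ± 8.90 CPM in fl/fl and 45.0 ± 53.8 CPM in iGKO, with 126 CPM in iGKO sham 2 and 13.2 to 21.7 CPM in the other iGKO sham libraries.

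In 8 lists called by camera, no gene was called, also when adjusted over the list alone. Tubular injury markers were positive in 24 of 28 (median 0.43, adjusted p = 7.24e-06, adjusted p = 0.759 with an estimated correlation). Without iGKO sham 2 the adjusted p by camera was 0.0173. The injury score was 5.28 in iGKO sham 2, 4.41 to 4.86 in the other iGKO sham libraries and 4.09 to 4.52 in fl/fl sham. Mitochondrially encoded mRNAs were negative in 12 of 13 (median -0.31, adjusted p = 7.24e-06, adjusted p = 0.759 with an estimated correlation), and without iGKO sham 4, the library with 0.443% of counts in mitochondrially encoded genes, the direction reversed and the adjusted p was 0.496. Lymphocyte markers (median -0.45, adjusted p = 0.00406, adjusted p = 0.759 with an estimated correlation) lost their call without iGKO sham 2 (0.0831), and cytokines and chemokines (median 0.46, adjusted p = 0.0162, adjusted p = 0.759 with an estimated correlation) without iGKO sham 1 (0.480). Adrenal, fat, muscle and urothelium markers (median -1.46, adjusted p = 0.00632, adjusted p = 0.759 with an estimated correlation) lost it without fl/fl sham 1 (0.1) or 3 (0.0934) or iGKO sham 2 (0.0668) or 4 (0.0995). The fat gene Cfd stood at 0.908 to 168 CPM in fl/fl sham and 2.90 to 72.9 CPM in iGKO sham. Cholesterol synthesis (median -0.14, adjusted p = 0.0127, adjusted p = 0.985 with an estimated correlation) lost its call without fl/fl sham 1 (0.149) or 4 (0.127) or iGKO sham 1 (0.403). The integrated stress response (median 0.15, adjusted p = 0.0224, adjusted p = 0.759 with an estimated correlation) lost it without fl/fl sham 3 (0.0533) or 4 (0.365) or iGKO sham 3 (0.207) or 4 (0.0964). Erythrocyte markers (median -0.67, adjusted p = 0.0429, adjusted p = 0.845 with an estimated correlation) lost it without fl/fl sham 1 (0.927) or 2 (0.550), iGKO sham 2 (0.0573), 3 (0.343) or 4 (0.0995), fl/fl IRI 4 (0.0632), or iGKO IRI 2 (0.0506) or 4 (0.0545). Ceramide de novo synthesis had 1 gene lower adjusted over the list alone, Degs1, and a list adjusted p of 0.0528. With 1 library left out this ran from 0.0148 to 0.974. Degs1 is the deleted gene, and the list was not tested without it. Other uncalled lists crossed the threshold as well. The ranges were 0.000876 to 0.654 for fatty acid oxidation, 0.00518 to 0.542 for immediate early genes and 0.0171 to 0.929 for interferon-stimulated genes.

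The count of 0 came from edgeR, with 210 genes at an unadjusted p under 0.05, fewer than the 899 of chance. The model pooled the spread over all 4 groups. With the compared groups fitted alone, edgeR gave such a p for 356 of 16962 genes and called 0. DESeq2 called 0 genes, with 377 at an unadjusted p under 0.05, and limma voom called 2, Apoh (adjusted p = 0.0229) and Rnf24 (adjusted p = 0.0480), the latter named after its values were seen. On simulated data the same test recovered 89 of 100 genes changed by 4-fold and 53 of 100 changed by 2-fold. The simulation gave a gene the same spread in all libraries, unlike the real data, and changed no gene with a mean under 1 CPM. These shares may thus overstate what the test could find. Degs1, whose levels did not overlap between the groups, did not pass, so a count of 0 does not show an absence of effects. Over all tested genes 1.93% had no overlap between the groups, where chance gives 2.86%.

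The comparison of iGKO with fl/fl after IRI asked whether injured kidneys differ by genotype. Sox9 was lower in iGKO and stood at 85.2 ± 95.5 CPM in fl/fl and 4.08 ± 1.13 CPM in iGKO (n = 4 each), a log2 fold change of -4.38 ± 0.68 (SE) with an adjusted p of 0.0325. Cxcl1 stood at 32.8 ± 23.5 and 3.05 ± 1.03 CPM, Clu at 1349 ± 719 and 355 ± 78.9 CPM, and Lcn2 at 249 ± 157 and 43.7 ± 13.2 CPM. Sptlc2 was lower in iGKO, at 280 ± 128 and 128 ± 19.4 CPM (adjusted p = 0.0398), and Cyp4a14, a fatty acid hydroxylase gene, was higher, at 273 ± 120 and 1025 ± 243 CPM (adjusted p = 0.0453). No gene was called, with a count of 0, without fl/fl sham 4, fl/fl IRI 3, fl/fl IRI 4, iGKO IRI 1, iGKO IRI 2 or iGKO IRI 3.

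Of 28 tubular injury markers 12 were lower (21 adjusted over the list alone, median -1.79, adjusted p = 2.02e-16, adjusted p = 0.202 with an estimated correlation). Among them were Il34, a macrophage growth factor, and the surface marker Cd24a, at log2 values of -2.41 and -1.66. Havcr1 stood at 950 ± 691 and 84.6 ± 40.8 CPM and did not pass (log2 -3.49, adjusted p = 0.0615). In fl/fl IRI 1, Havcr1 was 101 CPM, within the range of the iGKO IRI libraries. The exact two-sided permutation test of the injury score, 7.06 ± 0.86 in fl/fl and 5.60 ± 0.24 in iGKO (n = 4 each), gave p = 0.0286, the smallest it can give, and 0.192 after adjustment over 37 lists. The margin between the groups was narrow, with the lowest fl/fl score at 5.85 in fl/fl IRI 1 and the highest iGKO score at 5.77 in iGKO IRI 2. Immediate early genes were lower in 6 of 20 (18 adjusted over the list alone, median -1.36, adjusted p = 1.64e-15, adjusted p = 0.202 with an estimated correlation). Jun stood at 158 ± 62.0 and 66.4 ± 5.22 CPM, with Maff, Klf6 and Btg2 at log2 values of -2.18, -1.97 and -1.72. Neutrophil markers had none called and 7 lower adjusted over the list alone (median -2.11, adjusted p = 0.00018, adjusted p = 0.356 with an estimated correlation). The heat shock list had none called and 7 lower adjusted over the list alone (median -0.41, adjusted p = 0.000349, adjusted p = 0.318 with an estimated correlation). The p53 list had none called and 6 lower adjusted over the list alone (median -0.54, adjusted p = 0.000504, adjusted p = 0.253 with an estimated correlation). Cdkn1a in the p53 list had a log2 value of -2.14 (adjusted p = 0.0561). NRF2 and antioxidant genes were lower in 2 of 19, Hmox1 and Srxn1 at -1.76 and -1.97 (8 adjusted over the list alone, median -0.49, adjusted p = 0.0007, adjusted p = 0.356 with an estimated correlation). Regulated cell death had none called and 3 lower adjusted over the list alone (median -0.29, adjusted p = 0.0205, adjusted p = 0.318 with an estimated correlation).

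Proximal tubule markers were positive in 25 of 28, with none called and 9 higher adjusted over the list alone (median 0.66, adjusted p = 2.3e-09, adjusted p = 0.318 with an estimated correlation), and Slc34a1 stood at 1995 ± 1293 CPM in fl/fl and 3319 ± 455 CPM in iGKO (adjusted p = 0.240). All 10 thick ascending limb markers were positive, with none called and 5 higher adjusted over the list alone (median 1.04, adjusted p = 1.74e-07, adjusted p = 0.202 with an estimated correlation). Slc12a1 stood at 126 ± 79.1 and 362 ± 137 CPM (adjusted p = 0.0657), and Umod at 1371 ± 472 and 1989 ± 688 CPM without passing. Distal convoluted and connecting tubule markers had none called, 5 higher and 1 lower adjusted over the list alone (median 0.81, adjusted p = 0.00694, adjusted p = 0.356 with an estimated correlation). The collecting duct had none called and 2 higher adjusted over the list alone (median 0.38, adjusted p = 0.0128, adjusted p = 0.318 with an estimated correlation). In the lists of complex I, of complexes II, III and IV, of ATP synthase, of cristae and MICOS and of the tricarboxylic acid cycle, no gene was called or passed when adjusted over the list alone. The medians were 0.35 for complex I (adjusted p = 3.4e-06, adjusted p = 0.356 with an estimated correlation), 0.29 for complexes II, III and IV (adjusted p = 0.0007, adjusted p = 0.357 with an estimated correlation) and 0.31 for the tricarboxylic acid cycle (adjusted p = 0.000247, adjusted p = 0.357 with an estimated correlation). ATP synthase had a median of 0.27 (adjusted p = 0.00345, adjusted p = 0.357 with an estimated correlation), a call lost without iGKO IRI 4 (0.0601). Cristae and MICOS genes had a median of 0.24 (adjusted p = 0.0473, adjusted p = 0.405 with an estimated correlation), lost without fl/fl sham 1 (0.0507), 2 (0.0520) or 4 (0.0503), iGKO sham 2 (0.0507), fl/fl IRI 1 (0.0596), 3 (0.105) or 4 (0.127), or iGKO IRI 3 (0.102) or 4 (0.127). Ppargc1a stood at 58.4 ± 16.7 and 103 ± 14.9 CPM with an adjusted p of 0.0634 over all genes. Adjusted over the mitochondrial biogenesis list alone, it was higher and Pprc1 was lower, while the list was not called (adjusted p = 0.0561). Cholesterol synthesis genes were positive in 19 of 20, with none called and none adjusted over the list alone (median 0.64, adjusted p = 6.01e-05, adjusted p = 0.356 with an estimated correlation). Interferon-stimulated genes were positive in 19 of 20, with none called and 2 higher adjusted over the list alone (median 0.52, adjusted p = 5.17e-05, adjusted p = 0.318 with an estimated correlation).

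In ceramide de novo synthesis, 2 of 15 genes were lower, Degs1 and Sptlc2 (4 adjusted over the list alone, median -0.17, adjusted p = 0.0187, adjusted p = 0.356 with an estimated correlation), while Degs2 and Cers6 did not pass. The list holds Degs1, the deleted gene, so part of its shift was set by the design. It was not tested without Degs1, so the list p does not show a change in the rest of the pathway. Genes of ceramide use and breakdown had none called and 2 lower adjusted over the list alone (list adjusted p = 0.0695). Of 31 fatty acid oxidation genes Cyp4a14 was higher (1 adjusted over the list alone, median 0.26, adjusted p = 0.0228, adjusted p = 0.527 with an estimated correlation), and the list lost its call without fl/fl IRI 3, where the direction reversed (0.857), iGKO IRI 3 (0.0758) or iGKO IRI 4 (0.0592). Of 18 cytokines and chemokines Cxcl1 was lower (6 adjusted over the list alone, median -0.58, adjusted p = 0.0205, adjusted p = 0.363 with an estimated correlation), a list call lost without fl/fl IRI 2 (0.175) or 3 (0.0597). Of 16 monocyte and macrophage markers 14 were positive and Cd14 was lower, at 112 ± 109 and 21.4 ± 8.60 CPM (1 adjusted over the list alone, median 0.48, adjusted p = 0.0349, adjusted p = 0.49 with an estimated correlation), a list call lost without fl/fl IRI 4 (0.359), iGKO IRI 1 (0.139) or iGKO IRI 2 (0.171). Fibroblast and mural cell markers had none called and 3 higher adjusted over the list alone (median 0.75, adjusted p = 0.0128, adjusted p = 0.357 with an estimated correlation), a call lost without fl/fl IRI 1 (0.147) or iGKO IRI 2 (0.176), the library with 212 CPM of the fibroblast gene Dcn. Lymphocyte markers were positive in 8 of 8 with none called and none adjusted over the list alone (median 0.64, adjusted p = 0.0239, adjusted p = 0.357 with an estimated correlation), a call lost without fl/fl IRI 2 (0.152) or 4 (0.0730) or iGKO IRI 2 (0.0724) or 3 (0.0501). The other 13 lists were not called. Among them, mitochondrially encoded mRNAs had an adjusted p of 0.0832, and the list was called as lower without iGKO sham 4 (0.00344) or iGKO IRI 1 (0.0479). With 1 library left out, further uncalled lists crossed the threshold. The ranges were 0.00744 to 0.453 for adrenal, fat, muscle and urothelium, 0.0183 to 0.906 for extracellular matrix and 0.0184 to 0.409 for lysosome and autophagy. They were 0.0226 to 0.275 for mitochondrial biogenesis, 0.0257 to 0.820 for the cell cycle and 0.0350 to 0.148 for ceramide use and breakdown.

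The largest falls were Sprr2g, Sox9, Tmem252, Prrg4, Cxcl1, Chac1, Ctxn3, Lrp8, Gdf15 and Clcf1, at log2 values of -4.45, -4.38, -3.52, -3.45, -3.42, -3.40, -2.91, -2.66, -2.50 and -2.48. Gdf15, a stress-induced cytokine, stood at 77.4 ± 48.9 CPM in fl/fl and 13.7 ± 2.45 CPM in iGKO (n = 4 each). The largest rises were Col8a2, Kynu, Rnf212b, Fbln1, Axin2, Tenm2, Ptgds, Cyp4a14, Rapsn and C1qtnf2, at 3.06, 2.51, 2.46, 2.43, 2.19, 2.16, 2.07, 1.91, 1.89 and 1.88. Kynu, a kynureninase of tryptophan breakdown, stood at 5.17 ± 4.49 and 29.3 ± 5.71 CPM. The matrix gene Fbln1 stood at 3.37 ± 0.411 and 18.2 ± 14.9 CPM.

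In all, edgeR called 153 genes, 32 higher and 121 lower in iGKO, of which 129 differed at least 2-fold. Of these 153 genes, 112 had no overlap between the groups (5.52% of all tested genes had none, where chance gives 2.86%). The count was 0 without fl/fl sham 4, fl/fl IRI 3, fl/fl IRI 4, iGKO IRI 1, iGKO IRI 2 or iGKO IRI 3, and 2495 without fl/fl IRI 1. It was 31, 61 and 32 without fl/fl sham 1, 2 and 3, 27, 62, 67 and 235 without iGKO sham 1 to 4, 42 without fl/fl IRI 2 and 92 without iGKO IRI 4. None of the 33 named genes called here, Degs1 included, kept its call in every alternative. The balance of directions changed as well: 1282 genes were higher and 1213 lower without fl/fl IRI 1, 50 higher and 42 lower without iGKO IRI 4, and 88 higher and 89 lower without both iGKO sham 4 and iGKO IRI 4, a fit chosen after seeing the data. DESeq2 called 948 genes, 409 higher and 539 lower, and limma voom 1461, 681 higher and 780 lower. The count was 0 with the replicate number as a block or when the compared groups were fitted alone.

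The genotype by operation interaction asked whether the response to IRI itself differed by genotype. No gene passed the test. Among the genes of smallest p, none of which passed, were Clu, Plaur, the NF-kappaB regulator gene Nfkbiz and Myc, at log2 values of -2.35, -2.88, -1.86 and -2.56, each with an adjusted p of 0.244. Havcr1 had a value of -5.42 (adjusted p = 0.244), Lcn2 -3.13 (0.253), Sptlc2 -1.24 (0.262) and Degs1 -0.23 (0.754). Of 28 tubular injury markers 25 were negative, with none called and 19 lower adjusted over the list alone (median -2.42, adjusted p = 4.89e-22, adjusted p = 0.109 with an estimated correlation). Of 20 immediate early genes 19 were negative, with none called and 13 lower adjusted over the list alone (median -1.65, adjusted p = 2.35e-15, adjusted p = 0.196 with an estimated correlation). Proximal tubule markers were positive in 26 of 28 with none adjusted over the list alone (median 0.85, adjusted p = 3.67e-09, adjusted p = 0.284 with an estimated correlation). Thick ascending limb markers were positive in 10 of 10, with 6 higher adjusted over the list alone (median 1.06, adjusted p = 1.44e-07, adjusted p = 0.196 with an estimated correlation). The interaction of the injury score was -1.85, with an exact permutation p of 0.00286 and 0.0906 after adjustment over the lists. That test shuffled genotypes within each operation and was not planned beforehand. It assumes no genotype difference after either operation, so it is not a test of equal responses alone.

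The count of 0 came from edgeR, with 2033 genes at an unadjusted p under 0.05 and 899 by chance. It was 776 without fl/fl IRI 1, 113 with DESeq2 and 1163 with limma voom. On simulated data, with the same spread of a gene in all libraries, the interaction test recovered 8 of 100 genes changed by 2-fold and 71 of 100 changed by 4-fold. No gene with a mean under 1 CPM was changed there. The folds of the genotype comparisons after sham and after IRI had a Pearson r of -0.220 and a Spearman rho of -0.0708 across genes.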

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

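The counts of splits and the list tests of the interaction, also with a library left out, were planned. The other tests in this part were chosen after the results were seen. A library was set apart when its gap to the nearest library of its group was large against the range of the group by Dixon's test. This happened in 18 of 216 groups tested, where chance alone sets apart about 1 in 20, or 10.8.

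In library measures, the total of iGKO IRI 1 was 12704273 counts, against 14805417 to 15077208 in its group. The mitochondrially encoded share was 4.43% in fl/fl sham 2, against 6.14% to 6.48%, and 0.443% in iGKO sham 4, against 6.07% to 6.45%. In iGKO sham 4 the share of mitochondrial ribosomal RNA was 0.135% and that of the 10 most abundant genes 8.24%, against 2.16% to 2.25% and 12.0% to 12.6%. Havcr1 was 126 CPM in iGKO sham 2, against 13.2 to 21.7, and Cdkn1a was 36.9 CPM in iGKO IRI 3, against 23.6 to 25.5. In list scores, which are mean log2 levels, mitochondrially encoded mRNAs stood at 7.78 in fl/fl sham 2 and 4.96 in iGKO sham 4, against 8.13 to 8.15 and 8.03 to 8.28. Mitochondrial biogenesis regulators stood at 5.88 in fl/fl sham 2 and 5.97 in iGKO sham 4, against 5.78 to 5.79 and 5.79 to 5.81. The tricarboxylic acid cycle stood at 8.30 in fl/fl sham 1, against 8.20 to 8.21. In iGKO sham 3 the p53 response stood at 3.73 and the proximal tubule at 10.00, against 3.85 to 3.88 and 9.71 to 9.75. In iGKO IRI 1 the thick ascending limb stood at 5.91 and the erythrocyte at 4.31, against 6.60 to 6.69 and 5.10 to 5.24. The podocyte stood at 5.70 in fl/fl sham 2 and 4.83 in fl/fl IRI 4, against 5.42 to 5.45 and 5.45 to 5.49.

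The pattern weighed for iGKO sham 4 was its low mitochondrially encoded share of 0.443%. This library also stood apart in nuclear genes. Over 13413 nuclear protein-coding genes, its log2 difference from the other iGKO sham libraries correlated with GC content at r = 0.731. A GC trend thus ran through the whole library. Against the other iGKO sham libraries, its mitochondrially encoded mRNAs had a median log2 difference of -2.78, which argues against stronger depletion of ribosomal RNA as the whole cause, since that would leave the mRNAs in place. Of 1171 nuclear genes with the same GC content, 0% fell as far, with a median of -0.92, which argues against GC bias as the whole cause. Nuclear-encoded genes of complexes I to V had a median of -0.22 (SD 0.70 over 76 genes), which is not as low as that of the mitochondrially encoded mRNAs. The GC trend was not removed from these values and could hide a smaller fall. They therefore do not decide whether the piece was poorer in cells rich in mitochondria. A combination of causes was not tested and stays open, and no biological explanation was tested, since the labels set this library apart in no way.

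The response to IRI differed between genotypes in 22 lists by the camera test of the interaction, and each was no longer called with an estimated correlation (adjusted p from 0.109 to 0.446). The median log2 interaction was -2.42 for tubular injury markers, -1.65 for immediate early genes, -1.72 for cytokines and chemokines, -1.71 for neutrophil, -0.54 for the p53 response, -0.46 for heat shock, -0.45 for NRF2, -0.31 for regulated cell death and -0.18 for the integrated stress response. It was 0.85 for proximal tubule, 1.06 for thick ascending limb, 0.72 for distal convoluted and connecting tubule, 0.28 for collecting duct, 0.32 for complex I, 0.28 for complexes II, III and IV, 0.26 for ATP synthase and 0.30 for the tricarboxylic acid cycle. It was 0.67 for cholesterol synthesis, 0.36 for interferon-stimulated genes, 0.66 for fibroblast and mural cell, 1.37 for lymphocyte and 3.67 for adrenal, fat, muscle and urothelium. That last list marks possible neighbours of the tissue piece. Its fat gene Cfd ran from 0 to 48.7 CPM in fl/fl IRI and from 1.04 to 555 CPM in iGKO IRI. Neighbouring tissue in single pieces was thus not told apart from a response to IRI. The list call was lost for ATP synthase without fl/fl IRI 3 (0.0731) or iGKO IRI 4 (0.148), for regulated cell death without iGKO sham 1 (0.0565) and for fibroblast and mural cell without fl/fl IRI 1 (0.0637). For the integrated stress response it was lost without fl/fl sham 4 (0.140), iGKO sham 3 (0.0821) or 4 (0.0783), fl/fl IRI 3 (0.0522), or iGKO IRI 1 (0.0547) or 2 (0.102). For the collecting duct it was lost without fl/fl sham 2 (0.0645), iGKO sham 1 (0.0511) or 3 (0.0579), fl/fl IRI 2 (0.0612) or 3 (0.0855), or iGKO IRI 1 (0.0528), 3 (0.0543) or 4 (0.0627).

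For the smaller response of injury markers in iGKO, raised markers in sham iGKO kidneys were weighed first: the injury score of iGKO lay below that of fl/fl by -1.45 after IRI and above it by 0.40 after sham, so the sham level cannot be the whole cause. GC bias is argued against by a median of -1.77 over the injury markers after IRI with offsets corrected for GC content, against -1.79 without them. Uneven ischaemia between mice cannot be told apart from the genotype: the gap after IRI was 1.69 times the SD within fl/fl IRI, a group that held fl/fl IRI 1 at a Havcr1 of 101 CPM beside 710 to 1666 CPM. The labels give no measure of ischaemia for each mouse, which keeps this open, beside an effect of the genotype.

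The pattern weighed for iGKO IRI 2 was its high level of matrix and fibroblast genes, such as Col1a1 at 3598 CPM, Dcn at 212 CPM and Lum at 79.3 CPM. For capsule mesothelium or fat in the piece, 2 libraries had more of both markers, fl/fl sham 1 and fl/fl sham 3. The higher of their matrix scores differed from that of iGKO IRI 2 by -1.67, where the SD in the other groups was 0.29. Both were sham libraries, which do not tell how much matrix RNA such tissue holds after IRI, so they cannot decide this. Among IRI libraries, iGKO IRI 2 had the highest mesothelium score, 3.47, against 2.11 in iGKO IRI 3. In iGKO IRI 3 the fat score was higher, 7.10 against 4.55, with a matrix score of 6.97 against 7.98. In fl/fl sham 1, the mesothelial genes Muc16 and Msln stood at 60.4 and 20.2 CPM beside Col1a1 at 245 CPM, and in iGKO IRI 2 at 16.9 and 14.4 CPM. GC bias is argued against by a median excess of 1.38 after the GC trend was removed, against 1.26 before. A stronger matrix response in this mouse and a piece with more connective tissue of another kind were not tested and stay open, beside capsule tissue of an injured kidney.

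For the counts, other splits of the same libraries were fitted. For IRI against sham in fl/fl, 1 of 35 splits, the real one, gave 2779 genes and the highest other gave 1. The real grouping stood out, but 1 of 35 is the lowest share possible and does not by itself exclude chance. The other splits mix sham with IRI libraries, which widens the spread within their groups, so the size of the gap is partly built in. For iGKO against fl/fl after IRI, 2 of 35 splits gave at least the real 153 genes, and chance is not excluded. The highest other, with 1023 genes, put fl/fl IRI 1 with iGKO IRI 2, 3 and 4, and so many calls point to a structure of the samples. A count of 0 is reached by every split whatever the data, so for 3 comparisons the splits decide nothing: 35 of 35 for IRI against sham in iGKO (highest other 3), 35 of 35 for the genotypes after sham (highest other 0) and 100 of 100 drawn for the interaction (highest other 1). In the list tests, 1 of 35 splits gave at least the real 24 lists after IRI, with 23 as the highest other. That margin of 1 list is smaller than the range of 21 to 28 lists when 1 library was left out, so chance is not taken as excluded. Nor is it excluded for fl/fl (5 of 35, real 23, highest other 24), iGKO (6 of 35, real 19, highest other 21), the genotypes after sham (10 of 35, real 8, highest other 16) or the interaction (9 of 100, real 22, highest other 24).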

How the results depend on the processing

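The offsets corrected for GC content, the fit without iGKO sham 4 and iGKO IRI 4, and leaving out libraries outside the compared groups were chosen after seeing the data. List scores and library measures with a library left out were not planned either. Nor were other list score settings for IRI against sham and for the interaction. The other alternatives were planned beforehand. For results that changed, the cause was not tested. A fit to fewer libraries has less information on the spread, but this cannot be the cause of every change. Without fl/fl IRI 1 the count rose from 2779 to 4335 for IRI against sham in fl/fl and from 153 to 2495 for the genotypes after IRI. Depth limits genes of low counts, and Il6 was not tested. On simulated data the interaction recovered 8 of 100 changes of 2-fold. With limma voom the counts of called genes were 4593 for IRI against sham in fl/fl, 550 in iGKO, 2 for the genotypes after sham, 1461 after IRI and 1163 for the interaction. With DESeq2 they were 43 in iGKO, 948 after IRI and 113 for the interaction. With no filter they were 4 in iGKO (Abcc3, Capg, Tnc and Igdcc4), 352 after IRI and 15 for the interaction. When the compared groups were fitted alone, they were 1526 in fl/fl and 0 after IRI, where Degs1 had a log2 value of -1.02 (adjusted p = 0.317). With the replicate number as a block, they were 0 after IRI, where the smallest adjusted p was 0.0524 and Degs1 had a log2 value of -1.04 (adjusted p = 0.0544), and 1 for the interaction, Slc14a1, a gene named after its values were seen. The labels do not say that the numbers pair mice, and the residuals of 6 of 24 library pairs of the same number correlated above 0.1, with a mean of 0.0222 against -0.00519 for other pairs. With GC-corrected offsets 357 genes were called after IRI.

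Leaving out 1 library at a time gave 1452 to 4335 genes in fl/fl, 0 to 1 in iGKO, 0 to 0 after sham, 0 to 2495 after IRI and 0 to 776 for the interaction. In fl/fl the count moved over 1.5 times without fl/fl sham 1 (1691), 3 (1452) or 4 (1597) or fl/fl IRI 1 (4335), 3 (1459) or 4 (1850). After IRI the count was 0 without fl/fl sham 4, fl/fl IRI 3 or 4, or iGKO IRI 1, 2 or 3, and 2495 without fl/fl IRI 1, 31, 61 and 32 without fl/fl sham 1, 2 and 3, 27, 62, 67 and 235 without iGKO sham 1 to 4, 42 without fl/fl IRI 2 and 92 without iGKO IRI 4. The 1 gene in iGKO came without iGKO IRI 4, and the 776 of the interaction without fl/fl IRI 1. The log2 value of Degs1 ran from -0.95 to -0.68 after sham and from -1.15 to -0.96 after IRI, where the call was lost without fl/fl sham 4 (0.0508), fl/fl IRI 3 (0.0865) or 4 (0.0994), or iGKO IRI 1 (0.0734), 2 (0.0943) or 3 (0.133).

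The lists called by camera fell to 0 in all 5 comparisons with an estimated correlation. With fry they were 22 in fl/fl (23 with camera), 0 in iGKO, 0 after sham, 7 after IRI and 0 for the interaction, and without iGKO sham 4 and iGKO IRI 4 they were 5 after sham. Leaving out 1 library gave 21 to 24 lists in fl/fl, 14 to 21 in iGKO, 5 to 9 after sham (5 without fl/fl sham 1 or iGKO sham 4), 21 to 28 after IRI and 20 to 23 for the interaction. The list of mitochondrially encoded mRNAs reversed after sham without iGKO sham 4 and iGKO IRI 4 (adjusted p = 0.395) and without iGKO sham 4 alone, with a range of 1.57e-08 to 0.496 over the left-out libraries. In the interaction it reversed in the same fits (adjusted p = 0.0386 without both libraries and 0.00491 without iGKO sham 4, in a range of 0.00491 to 0.978). Fatty acid oxidation after IRI reversed without fl/fl IRI 3 (range 0.000187 to 0.857). List scores past the adjusted threshold were 0 to 0 in each comparison of groups and 0 to 5 for the interaction, with 2 without iGKO sham 3 and 5 without fl/fl IRI 1.

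Over all alternatives the named genes gave 19980 values on the same side of the threshold, 572 that lost and 549 that gained a call, 122 that moved and 0 that reversed. List tests gave 3607 alike, 270 lost, 80 gained, 103 moved and 5 reversed. List scores gave 2212 alike, 7 gained and 112 moved, and library measures 30 alike, 1 gained and 1 moved. Of the named genes called in fl/fl, 91 of 129 kept their call in every alternative, and 0 of 33 after IRI.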

Other observations

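Matrix and macrophage lists were not called in the main fit of the interaction. The extracellular matrix list had a median log2 response to IRI of 0.53 in fl/fl and 1.15 in iGKO, and a median interaction of 0.48 (adjusted p = 0.45; 2 genes higher and 1 lower adjusted over the list alone). Tnc, which encodes a matrix glycoprotein of healing tissue, reached 75.9 ± 55.6 CPM in fl/fl IRI and 73.2 ± 30.4 CPM in iGKO IRI (SD, n = 4 each). The monocyte and macrophage list had medians of 0.44 and 1.02 and a median interaction of 0.44 (adjusted p = 0.0571; none higher and 1 lower adjusted over the list alone). Without fl/fl IRI 1 it was called as higher (0.00158), and without iGKO IRI 2 its adjusted p was 0.186. Cd68, a macrophage lysosomal protein, stood at 6.58 ± 3.03 CPM in fl/fl sham, 14.3 ± 4.41 CPM in fl/fl IRI, 6.51 ± 3.44 CPM in iGKO sham and 17.9 ± 11.5 CPM in iGKO IRI. Ccl2 stood at 3.90 ± 1.75 CPM in fl/fl IRI and 6.25 ± 1.83 CPM in iGKO IRI, with an interaction of 0.01 on the log2 scale (adjusted p = 0.999). The matrix list in iGKO included iGKO IRI 2, and without that library the interaction of the matrix list had an adjusted p of 0.624 with the direction of camera reversed from higher to lower. A p above the threshold does not show that these responses were alike.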
